A study of Homo sapiens with 3 samples.

How the data were processed

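Total RNA of 3 samples of Huh7 cells was labelled with Cy3 and hybridised to 1-colour Agilent miRNA arrays, per the labels' protocols. One sample had been treated with a non-targeting siRNA and 2 with different siRNAs against a single target gene, which is not reported here, and the groups were taken from the sample descriptions. The samples with targeting siRNAs are called siTarget-2 and siTarget-3 in place of their labels. The authors deposited each array's scanner output, whose values are intensity on a linear scale. Per the file headers it was made with Agilent Feature Extraction 9.5.3.1, and probe positions are given in hg18. The processed signal is the software's background-subtracted intensity per spot, and the total gene signal is its own summary over the probes of a miRNA. The deposited value table, whose scale is stated nowhere in the sources used here, was set against the total gene signal. All values above its floor of 0.01 (459, 456 and 515 of 821 entries) matched it within rounding. The value table is therefore linear and not scaled between arrays, with medians of 0.253, 0.310 and 0.722. Flag columns of the deposited files (unit: other) were used for detection, background and outliers.

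Control spots and spots with an outlier flag (5.70% of the miRNA spots in siNTC, 6.09% in siTarget-2 and 5.73% in siTarget-3) were left out, and no spot was saturated. Processed signals were averaged over the spots of a probe. Each array was divided by the 75th percentile of the 172 probes, of 2421, that were well above background in most of their spots on all 3 arrays. Values were then floored at 0.102 scaled units, the lowest scaled signal of a probe well above background (8.92 in the units of siNTC), converted to log2 and averaged over the probes of a miRNA, including probes that disagree, such as those of miR-7. Because floored probes enter this mean, it understates differences of dim miRNAs. Human miRNAs were tested if detected by the scanner software in siNTC or in both siTarget arrays, which gave 144, and 7 of these lay at the floor on all arrays.

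The siTarget arrays were compared with siNTC with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This leaves 1 residual degree of freedom, and the lone siNTC array is assumed to vary like the siTarget arrays. The difference with one siRNA alone has no replicate check. Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. The version with an estimated correlation has 1 residual degree of freedom and could hardly call any list. Under the 2 settings where most miRNAs lie at the floor on every array, those miRNAs were left out of the list tests. Likeness of the 2 siRNAs was set against 1000 simulated sets of arrays that share a control, with the spread taken from the difference between the siTarget arrays in 6 bins of signal. On simulated data for the comparison of siTarget with siNTC (144 miRNAs, 30 of them changed, 50 runs), the fit called 7.40% of changes of 0.585 on the log2 scale, 21.8% of changes of 1 and 42.0% of changes of 2, and 0.123% of unchanged miRNAs. With the 109 miRNAs above the floor on all arrays these shares were 6.20%, 22.8%, 45.6% and 0.0759%. The floor shrank mean estimates of these sizes to 0.477, 0.817 and 1.56.

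The tests, the lists and the rule for named miRNAs were fixed before the data were examined. Named are all detected members of the miR-7 and let-7 lists, up to 12 called miRNAs in each direction, filled up to 8 with uncalled ones that differ in the same direction with both siRNAs in order of the smaller difference, 2 to 4 detected members of each other list with the highest mean signal, up to 6 miRNAs detected in one group alone, and the 5 brightest. The lists were miR-7, let-7, hepatocyte, miR-17-92 and paralogs, miR-15/16, p53-linked, miR-200, miR-23/27/24, miR-29, miR-30, miR-99/100/125, miR-181, miR-221 with miR-222, miR-21, muscle, blood, endothelium, fibroblast, neuron, the chromosome 14 and 19 clusters, miR-371 with miR-372 and miR-373, mirtrons, other RNA fragments and GC-rich entries.

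Alternatives were a 75th percentile over all probes, no scaling, quantile normalization, normexp background correction with an offset of 50, the total gene signal and the value table, both scaled to their own 75th percentile over the entries detected on all arrays, the brightest probe of each miRNA, miRNAs detected on all arrays, no filter, a floor 4 times higher, an intensity trend and leaving out each siTarget array. Added after the data were seen were a lower floor at the lowest signal that is positive and significant, scaling to 5 positive control probes, the total gene signal divided by the 75th percentiles of the probes, and only miRNAs above the floor on all arrays. All 3 arrays lie on 1 slide and were scanned together, so neither slide nor scan can be a batch. Their positions on the slide differ, and position cannot be told apart from sample. miRNA names are those of the array design and can be old. Probes for viral miRNAs and controls entered no comparison of the groups.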

Results

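MicroRNAs (miRNAs) were profiled in Huh7 cells, a human hepatoma line, treated with small interfering RNAs (siRNAs). One sample received a non-targeting control siRNA (siNTC). Each of the other 2 received a different siRNA against a single target gene, and these are called siTarget-2 and siTarget-3. Each sample was hybridised to 1 array. The array carried probes for 723 human and 76 viral miRNAs, and 136 human miRNAs were detected in siNTC, 128 in siTarget-2 and 157 in siTarget-3. Detection on all 3 arrays was found for 120 human miRNAs, and 561 were detected on none. Of the spots for miRNAs, 11.1% were well above background in siNTC, 10.3% in siTarget-2 and 13.0% in siTarget-3. With 1 control array and 2 siTarget arrays, the number of arrays limits the precision. The array holds no probe for the mRNA of the target, so its depletion was not checked here. The labels do not say that the siTarget samples came from separate cultures, so p-values of the fits rest on the spread between these 2 arrays, partly pooled across miRNAs. The 2 arrays also carry different siRNAs.

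The brightest entries by the mean over the 3 arrays were miR-923, miR-21, miR-122, miR-19b and miR-638. Their total gene signals in siNTC, before scaling, were 6525 for miR-923, 3338 for miR-21, a miRNA abundant in many tumour lines, and 864 for miR-122, the main miRNA of hepatocytes. Those of miR-19b and miR-638 were 561 and 228. miR-923 is an entry reported to come from ribosomal RNA and not from a miRNA gene. Its total gene signal was 8228 in siTarget-2 and 12151 in siTarget-3.

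The first comparison asked which miRNAs differ between cells treated with targeting siRNAs and control cells. Compared to siNTC, miR-629*, miR-638, miR-135a*, miR-1225-5p and miR-494 were higher with both targeting siRNAs. miR-21*, miR-27a, miR-122, miR-122* and miR-21 were lower with both. The mean log2 difference of miR-629* was 1.72 ± 0.55 (SE from the fit, n = 2 against 1), a 3.28-fold higher signal. That of miR-21*, the passenger strand of miR-21, was -1.14 ± 0.34, a 2.21-fold lower signal. None of the 144 tested miRNAs passed an adjusted p of 0.05 in the limma fit, and the smallest adjusted p was 0.104. At an unadjusted p under 0.05, 2 miRNAs were higher (miR-663 and miR-483-5p) and 36 were lower. These numbers were 5 and 23 with quantile normalization, 0 and 5 without scaling, and 1 and 8 with scaling to positive control probes. The number of lower miRNAs thus depends on the scaling. With the total gene signal that the scanner software computes, scaled to its own 75th percentile, the numbers were 21 and 7. They were 12 and 48 with that signal and the scaling of the probes. miR-483-5p is named because of its p. Both siRNAs gave a higher signal than siNTC for 29 miRNAs and a lower one for 97.

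The fit had 1 residual degree of freedom, and 35 of the tested miRNAs lay at the signal floor on at least 1 array, which leaves some of them with no measured spread. When only the 109 miRNAs above the floor on all 3 arrays were fitted, a choice made after the data were seen, 3 were called higher and 14 lower at an adjusted p of 0.05. The 3 were miR-629*, miR-638 and miR-135a*. The 14 were miR-21, miR-21*, miR-122, miR-122*, miR-27a, miR-26b, miR-455-3p, miR-17, miR-20a, miR-19b, miR-92a, miR-29a and, named only because of this call, miR-103 and miR-96. Statements below that a miRNA or a member of a list did not pass refer to the fit of all 144. In that fit a small SE mostly reflects that the 2 siTarget arrays happened to agree, as little spread is pooled across miRNAs. miR-29a, for example, had an SE of 0.01 there and 0.13 in the fit above the floor.

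Among the miRNAs with the largest differences in the same direction with both siRNAs, none of which passed in the fit of all 144, the differences upward were wider for siTarget-3 than for siTarget-2. For miR-629* they were 1.32 with siTarget-2 and 2.11 with siTarget-3, and for miR-638 they were 0.67 and 1.05. miR-135a* differed by 0.56 and 0.83, miR-1225-5p by 0.54 and 0.99, and miR-494 by 0.46 and 0.84. miR-663, miR-134 and miR-1224-5p had mean differences of 0.38 ± 0.02, 0.45 ± 0.19 and 0.41 ± 0.15 (SE). Downward, miR-27a differed by -0.73 with siTarget-2 and -0.72 with siTarget-3, and its adjusted p was 0.104. miR-122 differed by -0.63 and -0.95, miR-122* by -0.62 and -0.87, and miR-21 by -0.60 and -0.87. The mean differences of miR-92a, miR-26b and miR-455-3p were -0.64 ± 0.08, -0.60 ± 0.04 and -0.58 ± 0.04 (SE). In the build the file headers give (hg18), the array's probe for miR-629* lies on chromosome 15 from 68158780 to 68158795. The probes for miR-27a, miR-122 and miR-21 lie on chromosome 19 from 13808261 to 13808277, on chromosome 18 from 54269303 to 54269321 and on chromosome 17 from 55273418 to 55273437.

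**Figure D1:**
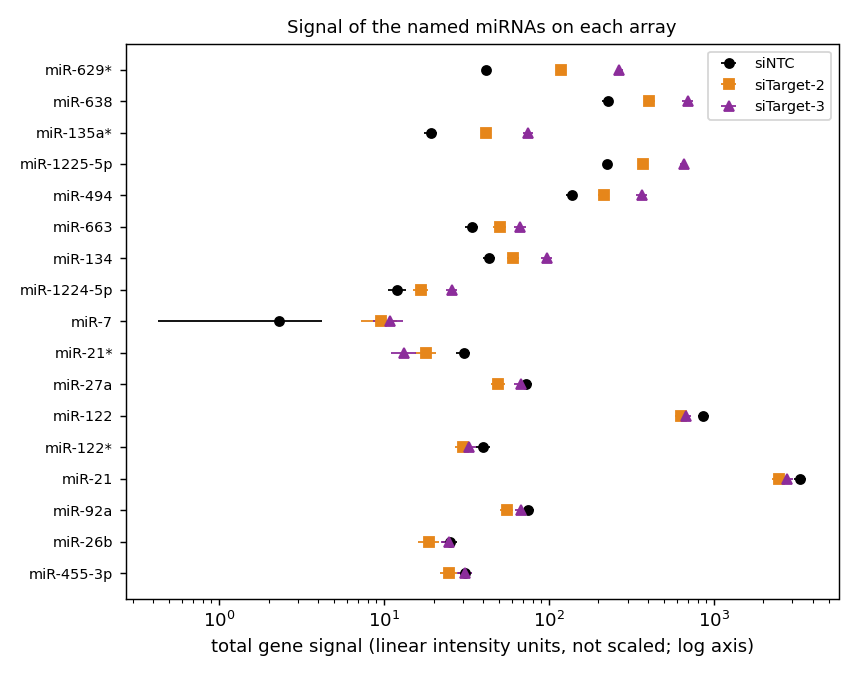
Total gene signal of miR-7 and of the 16 miRNAs with the largest differences in one direction with both siRNAs, in linear intensity units before scaling on a log axis, with 1 point per array and bars for the error the scanner software gives. miR-629* lies at 41.8 in siNTC, 118 in siTarget-2 and 267 in siTarget-3, and miR-7 at 2.32, 9.66 and 10.9.

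The difference was at least 2-fold with both siRNAs for 1 miRNA in the upward direction, miR-629*, and for 0 in the downward direction. miR-21* came close, at -0.90 with siTarget-2 and -1.38 with siTarget-3. With the total gene signal in place of the mean over probes, the log2 difference was at least 1 with both siRNAs for 7 miRNAs when it was scaled to its own 75th percentile, and for 4 with the scaling of the probes, a choice made after the data were seen. Only 3 of the 7 and 1 of the 4 were detected in siNTC, and the others, miR-7 among them, have no measured fold.

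The scaling sets the zero of these differences. The median difference of the 144 miRNAs was -0.14 on the log2 scale in the scaled data and 0.01 without scaling, a shift of 0.15. Without scaling the median difference with siTarget-2 was 0, the value of miRNAs at the floor on both arrays. The shift of the median therefore understates that of miRNAs above the floor. miR-192, for example, moved from -0.32 with scaling to 0.050 without it, and miR-16 from -0.25 to 0.12. The 75th percentile used for scaling was 87.7 in siNTC, 98.8 in siTarget-2 and 130 in siTarget-3. In the values without scaling, 47 miRNAs were higher and 28 lower with both siRNAs. Without scaling, the 8 miRNAs named for the largest differences in each direction lay on the same side of 0. With normexp background correction, which shifted the median by -0.49, miR-135a*, miR-663, miR-134 and miR-1224-5p turned to the lower side.

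miR-7, a miRNA that represses growth factor receptor signalling in several tumours, was examined on its own, because the published study followed it up. It was chosen on these samples and is therefore not independent evidence. miR-7 was not detected in siNTC and was detected with both targeting siRNAs. Its total gene signal was 2.32 ± 1.89 in siNTC, 9.66 ± 2.39 in siTarget-2 and 10.9 ± 2.23 in siTarget-3 (error given by the scanner software). On the log2 scale of the fit its difference was 0.33 with siTarget-2 and 0.23 with siTarget-3, with a mean of 0.28 ± 0.07 (SE), and it did not pass (adjusted p = 0.226, limma). This mean includes a second probe that was near background on all arrays. The brighter of its 2 probes had a mean signal of 4.98 ± 2.84 (SD over 7 spots) in siNTC, 15.9 ± 3.48 (8 spots) in siTarget-2 and 18.3 ± 1.43 (7 spots) in siTarget-3. It was not well above background in siNTC, so only a bound holds, and its scaled signal was at least 1.04-fold higher in siTarget. That bound sets the mean of both siTarget arrays against the higher of the probe's own siNTC signal and the lowest siNTC signal well above background. It does not hold for siTarget-3 alone, where the scaled signal of the probe was 0.140, below that lowest siNTC signal of 0.144. With the total gene signal in place of the mean over probes, scaled to its own 75th percentile, the difference was 2.01 ± 0.30 (SE), with an adjusted p of 3.78e-08. That SE is pooled over all miRNAs and does not measure the spread of miR-7 itself. With the scaling of the probes the difference was 1.77 (adjusted p = 0.0276). Since miR-7 was not detected in siNTC, neither value is a measured fold. With normexp background correction it was -0.65 and passed as lower (adjusted p = 1.61e-05), as did 118 miRNAs in all under that setting, where the median of the 144 was -0.62. Over all alternatives its adjusted p reached from 3.78e-08 to 0.985. The array's probe is placed on chromosome 15 from 86956092 to 86956113 in hg18. The passenger strands miR-7-1* and miR-7-2*, placed on chromosomes 9 and 15, were detected on no array. The position of the probe does not show which of these loci gave the signal.

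let-7 is a family of tumour-suppressor miRNAs. Of its 18 entries, 5 were detected on some array, all of them dim. let-7a had a total gene signal of 8.40 in siNTC, 7.19 in siTarget-2 and 8.30 in siTarget-3. Its difference in the fit was -0.24 ± 0.02 (SE), and it did not pass (adjusted p = 0.119, limma). That SE is small because let-7a lay at the floor in siTarget-3, at -3.30 on the log2 scale, and just above it in siTarget-2, at -3.27. let-7a was well above background in siNTC alone, and its scaled signal was at least 1.19-fold lower in siTarget as a mean of both arrays. That bound does not hold for siTarget-2 alone, where the lowest scaled signal well above background was 0.143, against 0.102 in siTarget-3. Before scaling, the signal of its brighter probe was 12.6 in siNTC, 10.4 in siTarget-2 and 12.2 in siTarget-3. let-7e differed by -0.14 ± 0.11, let-7b* by -0.01 and let-7f-1* by -0.04, and let-7f lay at the floor on all arrays. As a list let-7 gave no call (adjusted p = 0.673, camera), and its median, 0.10 above that of all tested miRNAs, had the opposite sign to the test statistic. No member passed when p was adjusted over the list alone.

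Of 25 lists of miRNAs fixed before the data were examined, 7 had at least 5 tested members. The list called GC-rich entries was fixed by name, and the GC content of its members was not computed. It was meant to hold entries that move with RNA input or quality on this kind of array, which was not tested here. The list was higher with targeting siRNAs relative to the other miRNAs (adjusted p = 0.000177, camera with a preset correlation). With an estimated correlation its adjusted p was 0.670 (camera), but that version has 1 residual degree of freedom and could hardly call any list. It does not decide whether correlation among the members accounts for the call. Of the 12 tested members of the list, 9 were higher and 2 lower with both siRNAs, and the median lay 0.51 above that of all tested miRNAs. Its brightest members were miR-638, miR-1225-5p, miR-494 and miR-630, with mean differences of 0.86, 0.76, 0.65 and 0.37 on the log2 scale. 0 members passed singly, over all miRNAs tested or adjusted over the list alone. The list shares 2 tested members with the mirtron list and 2 with the chromosome 14 cluster.

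miR-17, miR-20a, miR-19b and miR-92a belong to the proliferation-linked miR-17-92 polycistron, whose array probe for miR-17 lies on chromosome 13 from 90800879 to 90800895. They differed by -0.60 ± 0.06, -0.61 ± 0.08, -0.58 ± 0.07 and -0.64 ± 0.08 (SE). Together with its paralogs the list had 15 tested members. Of these, 13 were lower and 0 higher with both siRNAs, and 9 had an unadjusted p under 0.05. With an estimated correlation, which could hardly call any list, the adjusted p was 0.670 (camera). The list, whose test statistic turned its sign with normexp, missed the threshold with the preset correlation (adjusted p = 0.0538, camera), and 0 members passed when adjusted over the list alone. It passed, as lower, under 9 of 15 alternatives (adjusted p from 0.00163 to 0.784 over the 15). The brightest paralog named, miR-20b, differed by -0.47 ± 0.11. In the same arrays the median of the GC-rich list lay 0.51 above that of all tested miRNAs, and miR-923 differed by 0.26 ± 0.13 in scaled signal.

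Of the hepatocyte list, which holds miR-122, 8 of 9 tested members were lower and 0 higher with both siRNAs. The list did not pass (adjusted p = 0.277, camera), and neither did any member, also when adjusted over the list alone. miR-148a differed by -0.38 ± 0.03 (SE), and miR-192 by -0.32 ± 0.24 and miR-215 by -0.25 ± 0.22, both of which turned to the higher side without scaling. All 5 tested members of the clusters of miR-23, miR-27 and miR-24 were lower with both siRNAs, with no call for the list (adjusted p = 0.160). Besides miR-27a, miR-27b differed by -0.48 ± 0.03, miR-24 by -0.48 ± 0.10 and miR-23b by -0.20 ± 0.08. In this list 2 members, miR-27a and miR-27b, passed when adjusted over the list alone. Their SEs of 0.01 and 0.03 reflect close agreement of the 2 siTarget arrays, and both were 0.13 in the fit above the floor. All 5 tested p53-linked miRNAs were lower too (adjusted p = 0.345, camera), with miR-34a at -0.53 ± 0.10 and miR-107 at -0.36 ± 0.03. Of those named, miR-107, miR-192 and miR-215 turned to the higher side without scaling. The remaining member, miR-194, was not followed over the alternatives. No p53-linked miRNA or mirtron passed adjusted over the list alone. Neither direction was called for the mirtrons, with 2 of 10 tested members higher and 6 lower with both siRNAs (adjusted p = 0.277, camera). Mirtrons are described as a class made by splicing, which was not checked for the members of this list. miR-1228 differed by -0.04 ± 0.05 and miR-1234 by -0.13 ± 0.14, and both turned to the higher side without scaling. The mirtron list's median lay 0.11 above that of all tested miRNAs, and it passed, as higher, with quantile normalization (adjusted p = 0.0458) and with the 75th percentile over all probes (adjusted p = 0.0456), out of a range from 0.0456 to 0.981 over its alternatives. Both calls used the preset correlation of camera, and an estimated correlation was not run under the alternatives.

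**Figure D2:**
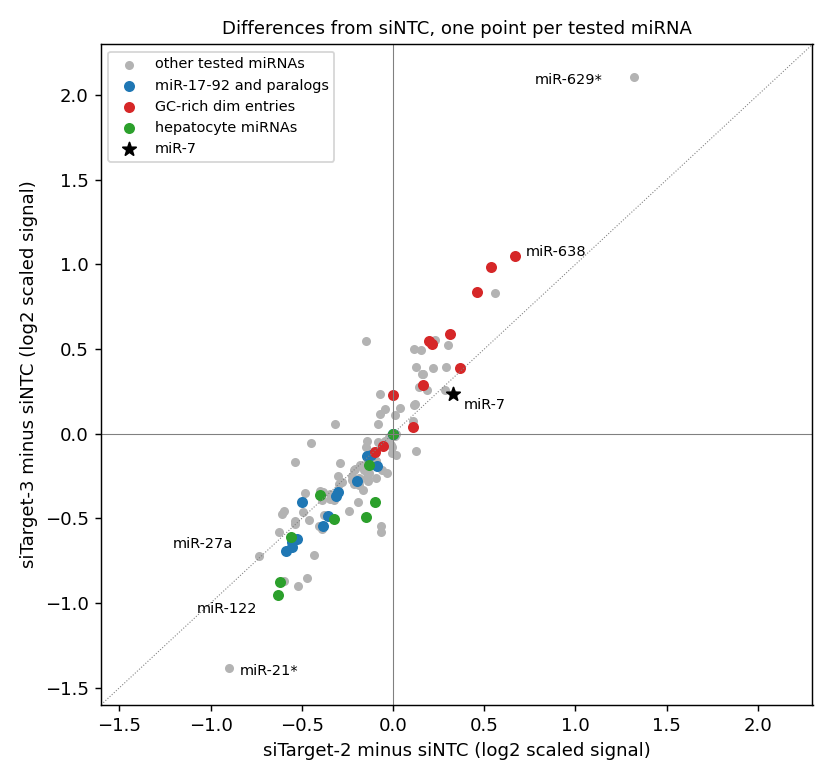
Difference from siNTC in log2 scaled signal for each of the 144 tested miRNAs, with siTarget-2 on the x axis and siTarget-3 on the y axis, coloured by list, and equality as a dotted line. The points spread along the line of equality (Pearson's r 0.917), the GC-rich entries lie toward the upper right, the hepatocyte and miR-17-92 miRNAs toward the lower left, and miR-629* lies apart at 1.32 and 2.11.

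Lists with fewer than 5 tested members were described without a test of the list. The miR-29 family had all 3 tested members lower with both siRNAs. miR-29a lay at -0.53 ± 0.01, miR-29b at -0.28 ± 0.04 and miR-29c at -0.48 ± 0.03 (SE), and 3 passed adjusted over the list alone. In the miR-30 family all 3 tested members were lower as well, miR-30e by -0.28, miR-30d by -0.25 and miR-30b by -0.22. miR-30d turned to the higher side without scaling, and miR-30e alone passed adjusted over the list alone. These passes rest on how closely the 2 siTarget arrays agreed. In the fit above the floor the SE was 0.13 for miR-29a, miR-29b, miR-29c and miR-30e alike. miR-30c was detected in siTarget-3 only. Of the miR-15/16 family, linked to cell cycle arrest, miR-16 differed by -0.25 ± 0.28, miR-15b by -0.35 ± 0.26 and miR-15a by -0.13 ± 0.27, all turned to the higher side without scaling, and the sign for miR-15a differed between the siRNAs. miR-200b, the only detected member of the epithelial miR-200 family, differed by -0.36 ± 0.05. These sizes depend on the floor for some miRNAs. With the lower floor miR-200b differed by -0.78 and miR-29b by -0.63, while miR-29a stayed at -0.53. miR-125a-5p differed by -0.30 (adjusted p = 0.104, limma) and was not well above background with either targeting siRNA. Its signal was at least 1.28-fold lower as a mean of both siTarget arrays, a bound that does not hold for siTarget-2 alone. miR-125a-3p differed by 0.25 ± 0.13. No member of the miR-181 family or of miR-221 and miR-222 was detected.

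Members of lists for other cell types were few and mostly dim, but miR-150* of the blood list had a total gene signal of 45.3 in siNTC. No endothelial miRNA was detected. Of the muscle list only miR-378 was tested, at -0.06 ± 0.02, and of the fibroblast list only miR-10b, at -0.23 ± 0.08. The blood list had miR-150* at -0.19 ± 0.04 and miR-146a at -0.25 ± 0.04, and miR-142-3p was detected in siTarget-3 only. Without scaling, miR-378, miR-10b and miR-150* turned to the higher side. From the neuron list, miR-129-3p and miR-129* differed by -0.18 and -0.21. Of the imprinted chromosome 14 cluster, 2 members were tested, miR-494 and miR-134, which also belong to the GC-rich list. The placental chromosome 19 cluster had miR-520b at 0.26 ± 0.19 and miR-520e at 0.31 ± 0.12. In the stem cell cluster, miR-371-5p differed by 0.09 ± 0.08 and miR-372 by -0.26 ± 0.06, and miR-373 lay at the floor on all arrays. miR-886-3p, an entry reported to come from a vault-like RNA, differed by -0.66 ± 0.27, opposite in sign to miR-923. miR-200b was the only tested member of its list, so no adjustment over the list alone applies to it (unadjusted p = 0.0346). Adjusted over the list alone, 2 members of the neuron list and miR-125a-5p passed, but these lay at the floor on both siTarget arrays, which leaves no measured spread, so the p is not a test of them. Adjusted in this way, 0 members of the miR-15/16, miR-21, muscle, blood, fibroblast, chromosome 14, chromosome 19, stem cell and other RNA fragment lists passed.

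Detection itself differed for 13 human miRNAs in a way that separated siNTC from both siTarget arrays. Detected with both targeting siRNAs and not in siNTC were 8, of which the brightest were miR-513a-5p, miR-557, miR-671-5p, miR-513b, miR-7 and miR-877. The total gene signal of miR-513a-5p was 3.59 in siNTC, 10.8 in siTarget-2 and 20.0 in siTarget-3, and that of miR-671-5p was 3.48, 8.01 and 16.1. Those of miR-557 and miR-513b were 6.90 and 4.09 in siNTC and 10.4 and 8.64 in siTarget-2. Detected in siNTC alone were 5, namely miR-1229, miR-33a, miR-92b, miR-373 and miR-183. All of them had a total gene signal of 6.86 or less in siNTC, before scaling. In the fit all 5 lay at the floor on both siTarget arrays. In siNTC, miR-92b and miR-373 lay at the floor as well, and the other members lay just above it. The differences of miR-1229, miR-33a and miR-183 were -0.01, -0.02 and -0.01. Detection calls, and hardly the signal in the fit, separate these 5.

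The last comparison asked whether the 2 independent siRNAs gave similar differences. Across the 144 tested miRNAs, which are not independent replicates, the differences from siNTC with siTarget-2 and siTarget-3 had a Pearson correlation of 0.917 and a Spearman correlation of 0.895, and 87.5% had the same sign, with the 7 miRNAs at the floor on all arrays counted as having none. Because both differences share the siNTC array, simulated arrays without any effect gave a mean Pearson correlation of 0.499, with 0.681 as the highest of 1000, a mean Spearman correlation of 0.462 and 66.6% of equal signs. The covariance was 0.119 against a simulated 0.0194, a difference of 0.0996. The simulation gives the siNTC array the same spread as the siTarget arrays, so it cannot cover a deviation particular to siNTC. The single control array could not be split, so part or all of the excess may come from the shared control.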

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

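Both tests on the GC-rich entries were written down before their result was seen. Probes for viral miRNAs, which Huh7 cells are not known to make, entered no comparison. Of 7 viral entries detected on all 3 arrays, 6 had a higher scaled signal with both targeting siRNAs than in siNTC, which is why they are listed. Their mean log2 differences were 0.60 for hcmv-miR-US4, 0.40 for ebv-miR-BART13, 0.36 for hsv1-miR-LAT, 0.23 for kshv-miR-K12-3, 0.20 for ebv-miR-BART16 and 0.035 for kshv-miR-K12-10a. The other entry, ebv-miR-BART12, was lower with both siRNAs (-0.31). Of the 5 positive control probes, 5 were lower in scaled signal with both siRNAs. The scaling sets this direction. Before scaling, their ratios to siNTC lay between 0.85 and 1.09 in siTarget-2 and between 0.95 and 1.19 in siTarget-3. The 75th percentiles used for scaling had ratios of 1.13 and 1.49.

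The viral entries bear on the higher signal of GC-rich entries in the siTarget arrays. A bias that follows signal strength is argued against, since the list's median lay at the 99.98th percentile of 10000 random lists matched on mean signal. Signal from RNA other than the named miRNAs remains open: it predicts that viral entries are higher as well, and their median lay 0.36 above that of all tested miRNAs, against 0.51 for the GC-rich list. This may reflect cross-hybridisation of other RNA fragments, of which more may be present in, or labelled from, the siTarget samples. An effect of depletion of the target on the RNA that hybridises also stays open, untested, and slide position cannot be told apart from treatment.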

How the results depend on the processing

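A lower floor, scaling to positive control probes, the total gene signal with the scaling of the probes and the fit of miRNAs above the floor on all 3 arrays were chosen after the data were seen. The GC-rich list passed, as higher, under all 15 alternatives with a preset correlation (adjusted p from 3.57e-07 to 0.0021). With an estimated correlation, which could hardly call any list and was not run under the alternatives, 0 lists passed. The number of lists that passed was 3 with the 75th percentile over all probes and with quantile normalization. It was 2 with the brightest probe, the higher floor, the lower floor, detection on all arrays, no filter, the total gene signal with the scaling of the probes, and miRNAs above the floor.

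The count of called miRNAs was 0 in each direction. With normexp 7 were called higher and 118 lower, where the offset is added before scaling and the median shifted by -0.49. With the total gene signal or the value table, each scaled to its own 75th percentile, 11 were higher and 1 lower, with the total gene signal and the scaling of the probes 1 and 0, with the lower floor 11 and 21, without a filter 2 and 39, above the floor 3 and 14, and with an intensity trend 0 and 6. Of the 17 calls above the floor, 12 were shared with the lower floor and 4 with the total gene signal. At an unadjusted p under 0.05, 5.26% of calls were higher, against 75% with the total gene signal or the value table, 26.4% with the lower floor, 20.5% above the floor, 20% with the total gene signal and the scaling of the probes, 19.1% without a filter, 17.9% with quantile normalization, 11.4% with the 75th percentile over all probes and 0% without scaling. Without scaling, however, only 5 miRNAs were lower at that p, and with control scaling 8, against 36. The lower floor shifted the median by -0.11, the total gene signal with the scaling of the probes by -0.16 and control scaling by 0.15. With control scaling miRNAs above the floor moved by more than the median, for example miR-192 from -0.32 to 0.053. The cause of these differences was not tested.

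A log2 difference of at least 1 with both siRNAs was found for 0 miRNAs with normexp, 7 with the total gene signal or the value table (3 of them detected in siNTC), 4 with the lower floor (2 detected in siNTC) and 4 with the total gene signal and the scaling of the probes (1 detected in siNTC), against 1. Those not detected in siNTC have no measured fold. With a single siTarget array the counts ranged from 1 to 2 higher and from 0 to 1 lower, with the higher counts when siTarget replicate 2 was left out. miR-7 differed by 2.01 with the total gene signal and with the value table, 1.77 with the total gene signal and the scaling of the probes, 0.75 with the lower floor and -0.65 with normexp. Its adjusted p ranged from 3.78e-08 to 0.985, it lay between 0.23 and 0.33 with a single siTarget array, and it had no value with the higher floor. The correlation of the siRNAs' differences was 0.855 without scaling, 0.971 with normexp and 0.957 with the higher floor. No paired analysis was possible because the groups share no replicate numbers.

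Of the other comparisons of named miRNAs and lists with an alternative, 963 kept their direction and their side of the threshold, 139 passed only in the alternative and 65 turned their sign. With the 75th percentile over all probes these were miR-15a (0.018), miR-378 (0.015), miR-1228 (0.11) and miR-1234 (0.015). Without scaling they were miR-192 (0.050), miR-215 (0.12), miR-16 (0.12), miR-15b (0.020), miR-15a (0.24), miR-107 (0.0078), miR-30d (0.055), miR-378 (0.060), miR-150* (0.18), miR-10b (0.076), miR-1228 (0.33), miR-1234 (0.24) and let-7e (0.049), and the test statistics of the let-7 (mean against other miRNAs -0.10) and p53-linked (-0.10) lists turned to higher, while the p53-linked mean stayed below 0. With control scaling they were miR-192 (0.053), miR-215 (0.12), miR-16 (0.12), miR-15b (0.022), miR-15a (0.25), miR-107 (0.010), miR-30d (0.043), miR-378 (0.045), miR-150* (0.19), miR-10b (0.061), miR-1228 (0.33), miR-1234 (0.24) and let-7e (0.050), and in the same way the test statistics, not the p53-linked mean, of the let-7 (-0.10) and p53-linked (-0.097) lists. With quantile normalization they were miR-1228 (0.13) and miR-1234 (0.093). With normexp the miR-17-92 (0.086) and p53-linked (0.12) lists turned, as did miR-135a* (-0.21), miR-663 (-0.23), miR-134 (-0.050), miR-1224-5p (-0.57), miR-125a-3p (-0.54), miR-520b (-0.53), miR-520e (-0.63), miR-371-5p (-0.37), miR-513a-5p (-0.60), miR-557 (-0.66), miR-671-5p (-0.66), miR-513b (-0.67) and miR-877 (-0.70). With the total gene signal and with the value table, let-7b* (0.013), miR-15a (0.060), miR-378 (0.11), miR-1228 (0.22) and miR-1234 (0.11) turned. With the brightest probe miR-371-5p (-0.099) and miR-1228 (0.065) turned, with the higher floor miR-371-5p (-0.0069), and with a single siTarget array miR-15a ranged from -0.32 to 0.060. The cause was not tested. miRNAs at the floor on all arrays under a setting have no value there, and signal over background limits all dim entries.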

Other observations

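The test on spots of miR-7 was chosen after their values were seen, and the other tests were written down before. Within the miR-17-92 polycistron on chromosome 13, miR-17, miR-20a, miR-19b and miR-92a lay between -0.64 and -0.58 on the log2 scale. Its other tested miRNAs, named here after their values were seen, lay closer to 0, with miR-19a at -0.45, miR-17* at -0.32 and miR-18a at -0.14.

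Whether genomic neighbours differ alike was tested as a hypothesis. Over 52 pairs of tested miRNAs whose probes lie within 10 kb, arms of one hairpin left out, the median gap between the mean log2 differences was 0.19, against 0.31 when differences were shuffled among miRNAs (permutation p = 0.0251). This is consistent with shared primary transcripts, but 46 miRNAs entered these pairs, many of them from the miR-17-92 polycistron and its paralogs, whose similar sequences may also share probe signal. The same hypothesis for the arms of one hairpin was not borne out. Over 15 pairs the median gap was 0.27 against 0.30 for random pairs (permutation p = 0.367), which does not show that arms differ independently.

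miR-7 was near background in siNTC, and 2 technical explanations were tested. Scatter between spots is argued against, since the 8 spots of the brighter probe, outlier spots included, did not overlap between siNTC and either siTarget array (exact permutation p = 0.000155 for each, the smallest possible, two-sided), which covers the noise within arrays and says nothing on the spread between cultures. A rise of dim entries stays open. There were 126 human entries with a siNTC total gene signal within 2-fold of that of miR-7. Of these, 0% had scaled ratios with both siRNAs at least as high as the smaller ratio of miR-7, 3.14. But 110 of them were detected on no array, where a ratio decides nothing. The median ratio over the 126 was 0.67 with siTarget-2 and 0.64 with siTarget-3, which rests mostly on these undetected entries. The 4 detected with both targeting siRNAs were all undetected in siNTC, so choosing them favours higher ratios and they cannot count for a rise. Of these 4, 3 were higher with both. Their ratios with siTarget-2 and siTarget-3 were 2.67 and 3.75 for miR-513a-5p, 2.05 and 3.11 for miR-671-5p, and 1.88 and 2.34 for miR-513b. The other entry, miR-624*, had ratios of 0.81 and 1.06. A difference between arrays that is specific to this probe, such as cross-hybridisation, and an effect of depletion of the target, untested, both stay open.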
